A study of Mus musculus with 18 samples.

How the data were processed

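The series holds 18 Affymetrix Mouse Genome expression arrays (array version 2.0) of liver RNA from C57BL/6 mice, 3 for each combination of genotype (WT or AIM-KO) and diet (chow, 12 weeks of a high-fat diet or 20 weeks of it). AIM, the apoptosis inhibitor of macrophage, is the product of the gene Cd5l. Samples were grouped by the genotype and diet that their labels state. The labels call the samples biological replicates and do not say whether each came from a separate animal, so every p-value measures the spread between these samples. Per the labels the chow groups had 0 weeks of high-fat diet. Ages are not given, so time on diet and age cannot be told apart.

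The values used are the deposited intensity of each probe set, on a linear scale. Per the submitters' processing notes they are MAS5 values; the software version is not given in the sources used here. RNA was taken up in Trizol and labelled with biotin from 100 ng of total RNA, per the labels' protocols. The scaling target is known only from the values, whose 2% trimmed mean was 100 on each array. The table held 42 values equal to 0. The number of arrays limits the precision, and the median standard error of a comparison of 3 against 3 arrays was 0.22 on the log2 scale.

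Of 45101 probe sets, 64 were controls and were left out, 34945 had 1 gene in the platform annotation, 932 had several and 9160 had none. That annotation is old, so symbols were updated through the entrez id with a reference table of mouse gene names of assembly GRCm38.p6. It matched 34741 of the probe sets with 1 gene, and the other 204 kept the annotation's symbol. Probe sets with several genes or none were not named and entered no comparison of the report. No coordinates were used, because the build behind the annotation is not given in the sources used here; the reference table served only for names, chromosomes and the order of neighbouring genes.

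Intensities were transformed to log2(value + 3.3), where 3.3 is the 20th percentile of all values, so a log2 change understates the change of dim genes. No further normalization was applied. A probe set was kept if it lay above its array's 40th percentile on at least 3 arrays, which left 26674 probe sets with 1 gene, and each gene was represented by its brightest probe set. This gave 14694 genes.

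Each gene was tested with limma 3.58.1 in R 4.3.3, with 6 group means fitted on all 18 arrays, moderated variances with a trend on intensity, and 18.2 degrees of freedom including the prior. Comparisons were AIM-KO against WT on each diet and averaged over the 3 diets, each duration of the high-fat diet against chow within each genotype, 20 against 12 weeks averaged over genotypes, and the difference of each diet effect between the genotypes. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes are from limma, and those of gene lists are from its camera test.

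Fixed lists of genes, 35 in number and holding 560 members of which 475 were tested, were written with the design before the data were examined, as were the tests, the threshold, the filters and the rule for named genes. Each list was tested with camera at a preset correlation of 0.01 in each of 11 comparisons, and the 385 tests were adjusted together. The tests were repeated with a correlation estimated from the data, and fry, which asks whether a list's genes move one way on balance, was run beside them. The change given for a list is the median over its members. Counts of called members are given over all genes and adjusted over the list alone.

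Genes are named in the text by a rule. It takes Cd5l, up to 5 of the largest rises and falls past the threshold whose arrays did not overlap (with no such condition for averaged or interaction comparisons), all genes of a count of 5 or fewer, and, per list, up to 3 called members with the largest change or, where none was called, the member with the smallest p. Genes so named may be followed across diets and genotypes. Genes outside the rule are marked as chosen after their values were seen.

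The procedure was tested in 5 simulated runs. For AIM-KO against WT at 12 weeks it recovered 23.9%, 50.4% and 84.8% of genes changed 1.5-, 2- and 4-fold (4.5% of calls false). For the average over diets the shares were 57%, 83.9% and 98.8% (6.3% false), for 12 weeks against chow in WT 22.4%, 51% and 81.5% (5.3% false), for 20 against 12 weeks 47.5%, 72.8% and 95.8% (5.1% false), and for the difference of the 12 week diet effect 9%, 34.9% and 71.8% (4% false). A list shifted by 0.5 on independent noise was found in 5 of 5 runs.

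The alternatives tried were a pseudocount of 13.2 or 0.825, quantile normalization, no dim filter or a stricter one, the mean of a gene's probe sets, no variance trend, array weights, a replicate block, only the groups compared in the fit, a minimum fold of 1.5, the estimated list correlation, and leaving out each array in turn. Alternatives chosen after the data were seen were a term for the arrays with high Xist, leaving those arrays out, a term for the actin 3'/5' ratio, the chow and 12 week arrays alone, and WT alone for the effect of duration. Splits of the samples into other groups were counted for each comparison.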

Results

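Liver RNA of WT mice and of AIM-KO mice, which lack the macrophage-derived protein AIM, was measured on 18 arrays. The mice had been fed chow or a high-fat diet (HFD) for 12 or 20 weeks, with 3 arrays for each of the 6 groups. The comparisons ask how liver transcripts change with diet (or age) and how that differs without AIM. Median intensities ranged from 15 to 21.1 per array and the brightest probe set from 10002.9 to 16640. The correlation of arrays across probe sets was 0.955 to 0.98 within a group and 0.939 to 0.977 between groups. The few arrays limit the precision of every comparison. Changes are given on the log2 scale ± SE with n = 3 arrays per group, and intensities as mean ± SD.

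Cd5l, the gene that encodes AIM, read between 702.6 and 1926.8 on each of the 9 WT arrays and between 4 and 23.5 on each of the 9 AIM-KO arrays. Its AIM-KO to WT log2 change was -5.96 ± 0.35 on chow (adjusted p = 1.9e-08), -6.5 ± 0.35 at 12 weeks (adjusted p = 4.3e-09) and -6.7 ± 0.35 at 20 weeks (adjusted p = 2.6e-09). Whether the Cd5l probe set lies outside the deleted part of the gene is not given in the sources used here. In WT livers the Cd5l intensity was 746 ± 39.8 on chow, 1261 ± 313 at 12 weeks and 1599 ± 319 at 20 weeks. The change from chow was 0.73 ± 0.35 at 12 weeks (adjusted p = 0.27) and 1.08 ± 0.35 at 20 weeks (adjusted p = 0.047). The call at 20 weeks was kept in 1 of 6 fits that left out an array, the one without WT 20 weeks replicate 2 (adjusted p = 0.042), and ended with a term for the actin 3'/5' ratio (0.83, adjusted p = 0.21).

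Xist, the transcript that silences an X chromosome in female cells, separated the arrays at 20 weeks. It read 2921.6 to 3049.7 on all 3 AIM-KO arrays at 20 weeks and on WT 20 weeks replicate 2, and 7.8 to 26.2 on the other 14 arrays. On the same 4 arrays the Y-linked genes Eif2s3y, Kdm5d and Uty read 3.9 to 7.3, 1.7 to 9.9 and 1.4 to 5.8. On the other 14 they read 498.4 to 675.1, 71.8 to 131.8 and 82.3 to 159.9. The labels give no sex. Each comparison that involves AIM-KO at 20 weeks thus also differs in this respect. The actin 3'/5' ratio, a measure of RNA quality, was 3.47 ± 0.85 in WT and 2.5 ± 0.14 in AIM-KO at 20 weeks, and 3 ± 0.69 and 2.71 ± 0.3 at 12 weeks.

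**Figure D1:**
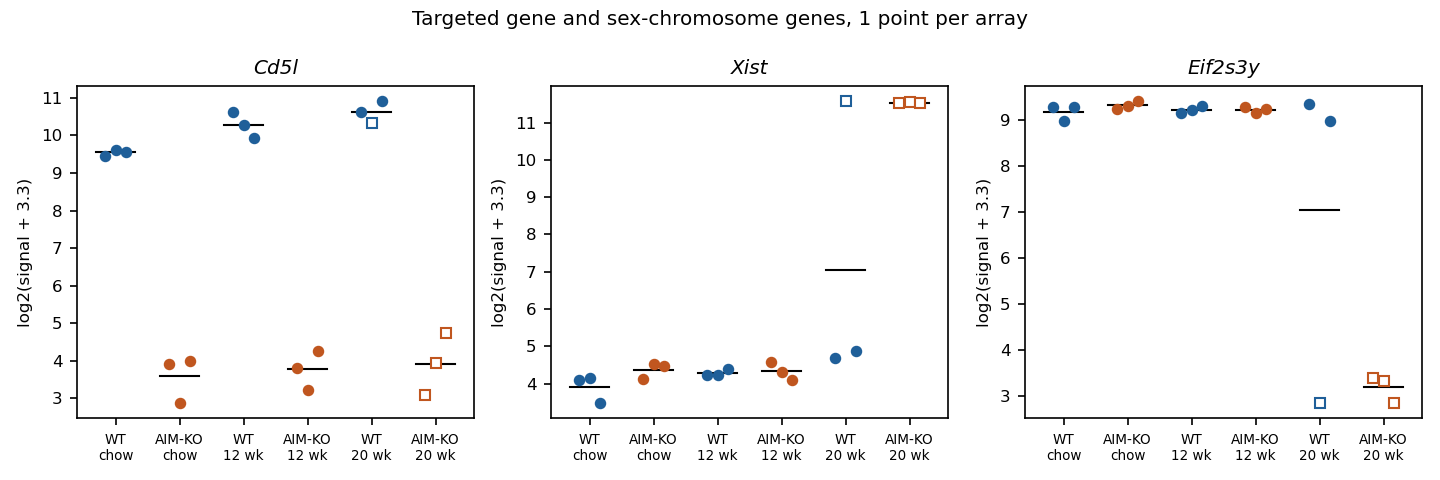
Intensity of Cd5l, Xist and the Y-linked gene Eif2s3y on each of the 18 arrays, on a log axis, with points for single arrays grouped by genotype and diet. Cd5l stays at or under 23.5 on all AIM-KO arrays, and Xist is at or above 2921.6 on the 3 AIM-KO arrays and 1 WT array at 20 weeks, where Eif2s3y is at or under 7.3.

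After 12 weeks of HFD, WT livers had higher levels of lipid storage genes. Cidea and Cidec, whose products coat and enlarge lipid droplets, rose by 6.83 ± 0.76 (adjusted p = 3.9e-05) and 5.4 ± 0.43 (adjusted p = 5.9e-07) against chow. Apoa4, an apolipoprotein of secreted lipid particles, rose by 3.51 ± 0.15 (adjusted p = 4.2e-11), from an intensity of 587 ± 98.9 to 6645 ± 240. The desaturase Fads2 rose by 1.78 ± 0.14, and the hormone gene Fgf21 by 1.71 ± 0.24. Among inflammation genes, the iron-binding protein gene Lcn2 rose by 3.79 ± 0.4, the serum amyloid genes Saa2 and Saa1 by 3.36 ± 0.42 and 2.23 ± 0.3, and the adhesion molecule Vcam1 by 1.86 ± 0.24. Mmp12, an elastase of macrophages, rose by 2.81 ± 0.43, the monocyte receptor gene Ccr2 by 1.9 ± 0.36, and the collagen gene Col3a1 by 2.34 ± 0.25. The proliferation gene Mki67 and the replication gene Mcm2 rose by 2.66 ± 0.43 and 1.91 ± 0.23, and Rad51b, a DNA repair gene, by 3.64 ± 0.32. The steroid dehydrogenase Hsd3b5, highest in male liver, changed by -5.71 ± 0.88 (adjusted p = 0.0007), and the lectin gene Clec2h by -3.9 ± 0.6. Lower too were Cyp26a1, which breaks down retinoic acid (-2.84 ± 0.32), the glucuronidation gene Ugt2b38 (-2.67 ± 0.36), the esterase gene Ces2a (-2.32 ± 0.23) and the complement gene C8b (-2.53 ± 0.31). The adjusted p of each gene named here was at most 0.0043, and each was called in all 6 fits that left out an array.

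In this WT comparison 753 of 14694 genes were called, 514 higher and 239 lower. The count fell to 413 without WT chow replicate 2, 478 without WT chow replicate 3 and 334 without WT 12 weeks replicate 1. Lipid droplet genes rose as a list (median log2 change 1.33, adjusted p = 1.2e-19, adjusted p = 0.046 with an estimated correlation), with 13 of 18 members called over all genes and 13 adjusted over the list alone. Fibrosis genes rose (0.74, adjusted p = 9.8e-11, adjusted p = 0.082 with an estimated correlation; 9 of 20 called, 12 adjusted over the list alone). Cell cycle genes rose by a median of 1.04 (adjusted p = 3.4e-09, adjusted p = 0.11 with an estimated correlation), with 9 of 22 called and 13 higher adjusted over the list alone. Recruited macrophage markers rose by 0.95 (adjusted p = 2e-08, adjusted p = 0.091 with an estimated correlation), with 8 of 15 called and 11 adjusted over the list alone. Fatty acid synthesis genes rose by 0.71 (adjusted p = 9.7e-06, adjusted p = 0.1 with an estimated correlation), with 4 of 18 higher and 11 adjusted over the list alone. Xenobiotic cytochromes P450 changed by -0.51 (adjusted p = 8.4e-08, adjusted p = 0.091 with an estimated correlation), with 7 of 15 lower and 10 adjusted over the list alone. Sex-biased genes moved although no array of chow or 12 weeks was Xist-high. Female-biased genes rose by 1.99 (adjusted p = 0.0016, adjusted p = 0.13 with an estimated correlation), with 2 of 6 called and 3 adjusted over the list alone. Male-biased genes changed by -1.14 (adjusted p = 3.8e-05, adjusted p = 0.15 with an estimated correlation), with 4 of 9 lower and 6 adjusted over the list alone. Without WT 12 weeks replicate 1 these values were 1.27 and -0.59. Hepatocyte markers changed by -0.13 (adjusted p = 0.0012, adjusted p = 0.45 with an estimated correlation; 0 of 13 called by limma, 4 lower adjusted over the list alone), by -0.04 after quantile normalization and by -0.24 to -0.05 without 1 array, and the call ended without WT 12 weeks replicate 1 (adjusted p = 0.056). In all, 20 of 35 lists were called.

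At 20 weeks of HFD, WT livers held the lipid droplet genes high, with Cidea at 5.92 ± 0.76 (adjusted p = 4.7e-05), Cidec at 5.31 ± 0.43 (adjusted p = 3.6e-07) and Apoa4 at 3.66 ± 0.15 (adjusted p = 1.9e-11) above chow. The extracellular matrix gene Dpt rose by 5.18 ± 0.57, the collagenase Mmp13 by 3.16 ± 0.55, the growth factor gene Ccn2 by 2.91 ± 0.24 and Col3a1 by 2.88 ± 0.25, the last from 122 ± 32.8 to 917 ± 216 in intensity. Macrophage genes rose as well, with Mmp12 at 4.38 ± 0.43, the lipid-associated marker Gpnmb at 2.66 ± 0.59 and the galectin gene Lgals3 at 2.64 ± 0.37. The chemokine gene Ccl2 rose by 2.59 ± 0.57, Vcam1 by 2.68 ± 0.24, the interferon-induced gene Ifit2 by 2.03 ± 0.22 and the class II antigen gene H2-Aa by 1.75 ± 0.3. Genes of immature liver and liver tumours, Ly6d and Sox4, rose by 4.9 ± 0.52 and 3.11 ± 0.38, and the cell cycle inhibitor Cdkn1a by 2.28 ± 0.47. Slco1a1, a bile acid uptake transporter, changed by -6.78 ± 0.97, the pseudogene Serpina4-ps1 by -6.18 ± 0.94 and the xenobiotic enzyme genes Cyp2c54 and Cyp1a2 by -5.41 ± 0.65 and -2.15 ± 0.19. Hsd3b5 changed by -9.41 ± 0.88, and the female-biased genes Cyp2b9 and Cyp17a1 rose by 5.29 ± 0.7 and 4.91 ± 0.43. WT 20 weeks replicate 2 was Xist-high. The adjusted p of each gene named here was at most 0.0054, and each was called in all 6 fits that left out an array.

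The WT comparison at 20 weeks called 2123 genes, 1276 higher and 847 lower. The actin 3'/5' ratio was 3.47 ± 0.85 against 2.67 ± 0.12 on chow. The count was 1397 without WT chow replicate 3 and 1403 without WT 20 weeks replicate 1. Fibrosis genes rose by a median of 1.5 (adjusted p = 2.8e-14, adjusted p = 0.053 with an estimated correlation), with 14 of 20 called and 15 adjusted over the list alone. Lipid droplet genes rose by 1.52 (adjusted p = 2.8e-14, adjusted p = 0.053 with an estimated correlation), with 12 of 18 called and 15 adjusted over the list alone. Recruited macrophage markers rose by 1.36 (adjusted p = 2e-09, adjusted p = 0.087 with an estimated correlation), with 12 of 15 called and 12 higher adjusted over the list alone. Interferon response genes rose by 0.72 (adjusted p = 2.7e-06, adjusted p = 0.14 with an estimated correlation), with 10 of 21 called and 12 higher adjusted over the list alone. Male-biased genes changed by -2.05 (adjusted p = 2.7e-07, adjusted p = 0.098 with an estimated correlation), with 8 of 9 called and 8 adjusted over the list alone. Their levels against WT chow were -2.26 and -2.03 on replicates 1 and 3 and -3.57 on the Xist-high replicate 2. Female-biased genes rose by 4.32 (adjusted p = 7.7e-05, adjusted p = 0.091 with an estimated correlation), with 4 of 6 called and 4 adjusted over the list alone. Complement genes changed by -0.37 (adjusted p = 1.7e-05, adjusted p = 0.13 with an estimated correlation), with 11 of 24 lower and 13 adjusted over the list alone. Hepatocyte markers changed by -0.14 (adjusted p = 0.006, adjusted p = 0.52 with an estimated correlation; 3 of 13 lower, 6 adjusted over the list alone), by -0.25 with the actin term or the mean of probe sets, by -0.08 with the Xist term, and by -0.08 and -0.23 without WT 20 weeks replicates 2 and 3. That call ended after quantile normalization (-0.06, adjusted p = 0.14) and without WT chow replicate 2 (-0.09, adjusted p = 0.062). In all, 19 of 35 lists were called.

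In AIM-KO livers at 12 weeks of HFD, Cidea rose by 6.01 ± 0.76 (adjusted p = 3.2e-05), Cidec by 5.23 ± 0.43 (adjusted p = 4.7e-07) and Mogat1, a triglyceride synthesis gene, by 3.26 ± 0.38 (adjusted p = 1.2e-05) against AIM-KO chow. Pdk4, which spares glucose during fat use, rose by 3.47 ± 0.52, the fatty acid synthesis gene Acacb by 2.38 ± 0.26 and the cholesterol synthesis gene Hmgcs1 by 1.37 ± 0.25. Ly6d rose by 5.9 ± 0.52, from an intensity of 14.5 ± 7.44 to 1014 ± 277, and Rad51b by 5.24 ± 0.32. Macrophage genes rose, with Mmp12 at 4.69 ± 0.43, Gpnmb at 3.3 ± 0.59, Lgals3 at 2.84 ± 0.37 and the lysosomal marker Cd68 at 1.05 ± 0.17. So did Mmp13 (4.52 ± 0.55), Col3a1 (2.57 ± 0.25), Ccl2 (2.79 ± 0.57), Lcn2 (4.42 ± 0.4), the interferon-induced genes Gbp2 (2.03 ± 0.35) and Oasl2 (1.62 ± 0.22), and the class II genes H2-Eb1 and H2-Aa (1.66 ± 0.3 and 1.65 ± 0.3). The stress genes Cdkn1a, Pmaip1 and Srxn1 rose by 3.02 ± 0.47, 1.91 ± 0.32 and 1.44 ± 0.26. Hsd3b5 changed by -8.52 ± 0.88 (adjusted p = 5.2e-06), Slco1a1 by -6.2 ± 0.97, Cyp2c54 by -5.65 ± 0.65, Clec2h by -5.1 ± 0.6 and the oxysterol hydroxylase Cyp7b1 by -2.69 ± 0.25. The urea cycle gene Cps1 changed by -0.85 ± 0.14 and the fibrinogen gene Fgb by -0.61 ± 0.11. Cd5l changed by 0.18 ± 0.35 (adjusted p = 0.79). Apart from Cd5l, the adjusted p of each gene named here was at most 0.002, and each was called in all 6 fits that left out an array.

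AIM-KO livers at 12 weeks had 2645 called genes, 1652 higher and 993 lower. Without AIM-KO 12 weeks replicate 1 the count was 1696, and without replicate 2 it was 1754. Lipid droplet genes rose by 1.48 (adjusted p = 2.4e-14, adjusted p = 0.053 with an estimated correlation), with 14 of 18 called and 16 adjusted over the list alone. Recruited macrophage markers rose by 1.32 (adjusted p = 1.1e-09, adjusted p = 0.087 with an estimated correlation), with 13 of 15 called and 13 adjusted over the list alone. Interferon response genes rose by 0.89 (adjusted p = 6.7e-07, adjusted p = 0.12 with an estimated correlation), with 12 of 21 called and 13 adjusted over the list alone. Endothelium markers rose by 0.36 (adjusted p = 0.0029, adjusted p = 0.29 with an estimated correlation), with 3 of 12 called and 5 adjusted over the list alone. Cytokine and chemokine genes rose by 1.02 (adjusted p = 9.4e-06, adjusted p = 0.1 with an estimated correlation), with 10 of 20 called and 10 adjusted over the list alone, by 0.63 with a pseudocount of 13.2 and by 0.62 with no dim filter. Target genes of p53 rose by 0.58 (adjusted p = 0.00019, adjusted p = 0.053 with an estimated correlation), with 5 of 11 called and 7 adjusted over the list alone. Bile acid genes changed by -0.63 (adjusted p = 3.3e-06, adjusted p = 0.082 with an estimated correlation), with 10 of 16 lower and 11 adjusted over the list alone. Hepatocyte markers changed by -0.4 (adjusted p = 2e-08, adjusted p = 0.19 with an estimated correlation), with 9 of 13 lower and 13 adjusted over the list alone, and by -0.12 after quantile normalization. Female-biased genes rose by 3.18 (adjusted p = 0.00072, adjusted p = 0.11 with an estimated correlation; 4 of 6 called, 4 adjusted over the list alone) and male-biased genes changed by -1.36 (adjusted p = 2.8e-06, adjusted p = 0.11 with an estimated correlation; 5 of 9 lower, 5 adjusted over the list alone). In all, 19 of 35 lists were called.

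At 20 weeks, where all 3 AIM-KO arrays were Xist-high and no AIM-KO chow array was, the largest changes in AIM-KO livers were in sex-biased genes. Cyp2b13, Hao2 and Cyp2b9, all female-biased, rose by 7.92 ± 0.79 (adjusted p = 5.4e-06), 6.95 ± 0.65 (adjusted p = 2.9e-06) and 6.56 ± 0.7 (adjusted p = 1.4e-05). With a term for the Xist-high arrays, resting on 1 WT array and leaving sex open, they rose by 3.66, 3.94 and 5.1, all past the threshold. Xist itself rose by 7.16 ± 1.08, the Y-linked gene Eif2s3y changed by -6.12 ± 0.99 and the male-biased cytochrome Cyp4a12a by -7.16 ± 1.11. The term took these to 0.37 (adjusted p = 0.68), 0.18 (adjusted p = 0.8) and -1.06 (adjusted p = 0.7). Lipid genes past the threshold with and without the term were the lipoprotein receptor gene Vldlr (3.21 ± 0.17), Apoa4 (2.8 ± 0.15), Acacb (2.44 ± 0.26) and Fads2 (1.6 ± 0.14). The same held for Lcn2 (3.35 ± 0.4), the interferon-induced gene Ifi27l2a (1.21 ± 0.26), Ly6d (3.47 ± 0.52), Col3a1 (1.51 ± 0.25) and the smooth muscle actin gene Acta2 of activated stellate cells (1.6 ± 0.25), with Ifi27l2a at 1.86 with the term. Hsd3b5, Cyp7b1, C8b and Ces2a were lower with and without it (-8.22 ± 0.88, -3.07 ± 0.25, -2.8 ± 0.31 and -1.93 ± 0.23). Alas2, the red cell haem synthesis gene, was lower too (-2.66 ± 0.24, -1.48 with the term). All genes named here were called in all 6 fits that left out an array, with adjusted p at most 0.0069.

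For AIM-KO at 20 weeks 1007 genes were called, 622 higher and 385 lower. The count was 586 without AIM-KO 20 weeks replicate 1, 538 without replicate 2, and 195 with the Xist term, of which 108 were shared. Female-biased genes rose by 5.71 (adjusted p = 7.6e-11, adjusted p = 0.046 with an estimated correlation), with 5 of 6 called and 5 adjusted over the list alone, and by 3.61 with the Xist term (adjusted p = 2.9e-05). Male-biased genes changed by -2.09 (adjusted p = 7.7e-12, adjusted p = 0.063 with an estimated correlation), with 7 of 9 lower and 7 adjusted over the list alone, and by -0.59 with the Xist term (adjusted p = 0.00072). Lipid droplet genes rose by 1.32 (adjusted p = 5.6e-14, adjusted p = 0.053 with an estimated correlation), with 10 of 18 called and 14 adjusted over the list alone. Fatty acid oxidation genes rose by 0.52 (adjusted p = 2.2e-11, adjusted p = 0.091 with an estimated correlation), with 11 of 20 called and 14 adjusted over the list alone, and by 0.26 with the Xist term (adjusted p = 0.018). Fibrosis genes rose by 0.87 (adjusted p = 1e-09, adjusted p = 0.087 with an estimated correlation), with 12 of 20 called and 14 adjusted over the list alone. Recruited macrophage markers rose by 0.47 (adjusted p = 0.0011, adjusted p = 0.26 with an estimated correlation), with 2 of 15 called and 3 adjusted over the list alone, and by 0.72 with the Xist term (adjusted p = 0.0085). Neutrophil markers rose by 0.77 (adjusted p = 0.042, adjusted p = 0.29 with an estimated correlation; 0 of 9 called by limma, 3 adjusted over the list alone). Their call ended with the Xist term (0.18, adjusted p = 0.97), a pseudocount of 13.2, the stricter dim filter or array weights (0.48, 0.97 and 0.4), and without AIM-KO chow replicate 1 or 3 or AIM-KO 20 weeks replicate 2 or 3 (0.74 to 1.03). Hepatocyte markers changed by -0.2 (adjusted p = 0.00014, adjusted p = 0.38 with an estimated correlation; 1 of 13 lower, 1 adjusted over the list alone), by -0.04 with the Xist term and by -0.03 after quantile normalization, which ended the call (adjusted p = 0.3). In all, 20 of 35 lists were called.

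Diet effects of WT and AIM-KO livers correlated across genes with r = 0.59 at 12 weeks and 0.56 at 20 weeks, from separate arrays, and genes are not independent replicates. Of 2808 genes called in either genotype at 12 weeks, 92.6% had the same sign in the other. Genes called higher in WT and in AIM-KO numbered 428 against 57.8 for independent lists, and lower 162 against 16.2. At 20 weeks the same sign held for 90.5% of 2530 genes, with 394 higher in each against 54 and 205 lower in each against 22.2, and 1 gene was called in opposite directions.

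**Figure D2:**
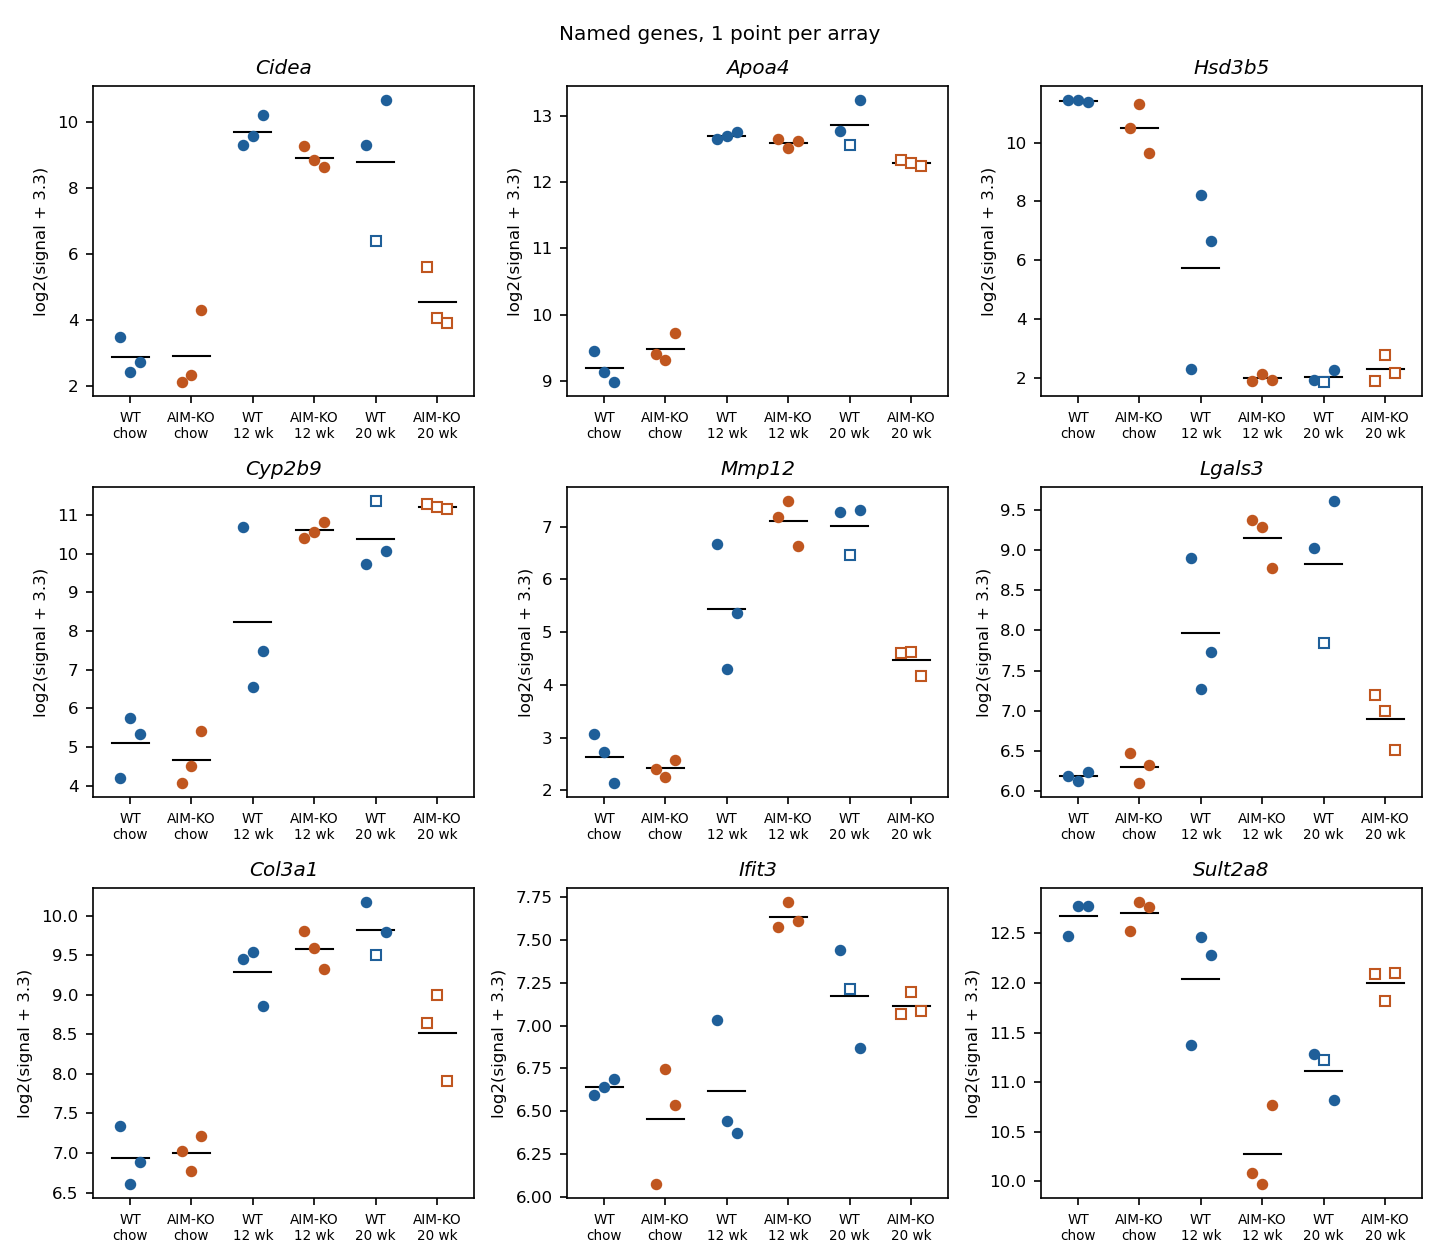
Intensity of genes named in the text on each array, on log axes, by genotype and diet, with points for single arrays. Apoa4 is near 6645 in WT and 6179 in AIM-KO at 12 weeks, whereas Cidea at 20 weeks averages 781 in WT and 23.6 in AIM-KO.

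On chow, the comparison of AIM-KO with WT asks what the loss of AIM does without the diet. Besides Cd5l, 3 genes were called. Asic5, which encodes a bile-acid-sensitive ion channel, rose by 3.25 ± 0.22 (adjusted p = 1.2e-07), from 53.3 ± 8.26 to 531 ± 29.4 in intensity. Papss1, which makes the sulfate donor of sulfation reactions, changed by -1.38 ± 0.14 (adjusted p = 5.1e-05), from 156 ± 17.6 to 58 ± 9.15. Selenbp1, a selenium-binding oxidase, changed by -0.63 ± 0.1 (adjusted p = 0.017), from 4867 ± 549 to 3136 ± 165. Cd5l and these 3 genes all lie on chromosome 3. Cd5l, Asic5 and Papss1 were called in all 6 fits that left out an array and Selenbp1 in 3. Over all genes, 1064 had an unadjusted p under 0.05. The count was 7 without each of the 3 AIM-KO chow arrays. Genes named for their lists stayed short of the threshold, among them the fat oxidation gene Cyp4a14 (-1.1 ± 0.22, adjusted p = 0.16), Vcam1 (0.95 ± 0.24, adjusted p = 0.28) and Ifit2 (0.83 ± 0.22, adjusted p = 0.3).

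As lists, interferon response genes were higher in AIM-KO on chow by 0.15 (adjusted p = 0.0026, adjusted p = 0.34 with an estimated correlation), with 0 of 21 called by limma over all genes and 1 adjusted over the list alone. The call ended without AIM-KO chow replicate 2 (0.06, adjusted p = 0.13), and the change was 0.3 and 0.09 without replicates 1 and 3 and 0.25 with array weights. Cholesterol synthesis genes were lower, at -0.24 (adjusted p = 0.017, adjusted p = 0.6 with an estimated correlation), with 0 of 19 called over all genes or adjusted over the list alone. Their change was -0.01 without WT chow replicate 1 (adjusted p = 0.6), -0.41 without WT chow replicate 2, -0.24 without AIM-KO chow replicate 2 (adjusted p = 0.18) and -0.19 with the mean of probe sets (adjusted p = 0.072). The other 5 list calls of the 7 on chow were endothelium markers (-0.2, adjusted p = 0.022), cytokines (0.24, adjusted p = 0.042), antigen presentation (0.13, adjusted p = 0.012), cell cycle (0.15, adjusted p = 0.049) and respiratory chain genes (0.07, adjusted p = 0.035). With an estimated correlation their adjusted p was 0.29 to 0.58, and each ended in at least 2 of the 6 fits that left out an array.

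At 12 weeks of HFD, AIM-KO livers differed from WT livers in single genes, and interferon and macrophage genes were called as lists, though not with an estimated correlation (adjusted p = 0.063 and 0.091). Asic5 was higher by 2.55 ± 0.22 (adjusted p = 6.6e-06). The interferon-induced genes Ifi207 and Ifit3 were higher by 1.29 ± 0.23 (adjusted p = 0.044) and 1.02 ± 0.19 (adjusted p = 0.047), Ifit3 at 196 ± 10.5 against 97 ± 26.7 in intensity. Klf6, a transcription factor induced by liver injury, was higher by 1.26 ± 0.23 (adjusted p = 0.044), and Jpt1, a microtubule-associated protein gene, by 1.17 ± 0.18 (adjusted p = 0.021). Cybb, the oxidase subunit of phagocytes, was higher by 0.78 ± 0.14 (adjusted p = 0.044), at 311 ± 16.2 against 182 ± 38. The sulfotransferase gene Sult2a8 differed by -1.77 ± 0.23 (adjusted p = 0.0022), at 1273 ± 403 against 4421 ± 1574. The steroid dehydrogenases Hsd3b2 and Hsd3b3, on chromosome 3 like Asic5 and Cd5l, differed by -1.4 ± 0.24 (adjusted p = 0.035) and -1.39 ± 0.23 (adjusted p = 0.028), and 1700066M21Rik by -0.6 ± 0.11 (adjusted p = 0.047). Short of the threshold were the pattern receptor gene Tlr2, also on chromosome 3 (1.06 ± 0.26, adjusted p = 0.17), the complement gene C1qb (0.85 ± 0.17, adjusted p = 0.065), Vldlr (0.78 ± 0.17, adjusted p = 0.11), the invariant chain gene Cd74 (0.61 ± 0.17, adjusted p = 0.23), Slco1a1 (-4.25 ± 0.97, adjusted p = 0.13) and Hsd3b5 (-3.74 ± 0.88, adjusted p = 0.15).

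These calls numbered 11, 6 higher and 5 lower, and 1229 genes had an unadjusted p under 0.05. Cd5l, Asic5 and Sult2a8 were called in all 6 fits that left out an array, and the other 8 in 1 or 2 of them. WT 12 weeks replicate 1 lay near the AIM-KO arrays in several measures. Its Hsd3b5 intensity was 1.6 against 293.8 and 97.2 on replicates 2 and 3, and its recruited macrophage markers stood 1.39 above WT chow against 0.81 and 0.78. Without it the count was 100. Without WT replicates 2 and 3 it was 4 and 3, and without AIM-KO replicates 1, 2 and 3 it was 3, 3 and 7.

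Interferon response genes were higher in AIM-KO at 12 weeks by a median of 0.63 (adjusted p = 7e-14, adjusted p = 0.063 with an estimated correlation), with 1 of 21 called over all genes and 12 adjusted over the list alone. Recruited macrophage markers were higher by 0.78 (adjusted p = 4.4e-08, adjusted p = 0.091 with an estimated correlation), with 1 of 15 called and 7 adjusted over the list alone. Cytokine and chemokine genes were higher by 0.46 (adjusted p = 1.3e-07, adjusted p = 0.091 with an estimated correlation), with 0 of 20 called over all genes and 7 adjusted over the list alone, and by 0.3 without WT replicate 3. Antigen presentation genes were higher by 0.38 (adjusted p = 2.3e-05, adjusted p = 0.1 with an estimated correlation), with 0 of 13 called and 6 adjusted over the list alone. Fetal liver and tumour markers were higher by 0.45 (adjusted p = 0.0015, adjusted p = 0.1 with an estimated correlation), with 0 of 14 called and 4 adjusted over the list alone, by 0.29 without AIM-KO replicate 2 and by 0.76 without replicate 3. Markers of T and NK cells were higher by 0.67 (adjusted p = 0.013, adjusted p = 0.1 with an estimated correlation), with 0 of 9 called and 2 adjusted over the list alone, by 0.39 with a pseudocount of 13.2 and by 1.04 with a stricter dim filter. Bile acid genes were lower, at -0.28 (adjusted p = 2.6e-06, adjusted p = 0.082 with an estimated correlation), with 0 of 16 called and 6 adjusted over the list alone. Male-biased genes were lower, at -0.6 (adjusted p = 5e-05, adjusted p = 0.16 with an estimated correlation), with 0 of 9 called and 4 adjusted over the list alone, and at -0.29 with the actin term. Hepatocyte markers were lower, at -0.25 (adjusted p = 4.6e-08, adjusted p = 0.2 with an estimated correlation), with 0 of 13 called over all genes or adjusted over the list alone, and at -0.08 after quantile normalization. These calls were kept in all 6 fits that left out an array, except that of T and NK cells, which ended without AIM-KO replicate 3 (0.69, adjusted p = 0.099). In all, 17 of 35 lists were called.

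At 20 weeks of HFD macrophage and fibrosis genes were lower as lists in AIM-KO than in WT livers, though not called with an estimated correlation (adjusted p = 0.091 each), and all 3 AIM-KO arrays and WT replicate 2 were Xist-high. The Mmp12 change was -2.55 ± 0.43 (adjusted p = 0.026), with intensities of 19.1 ± 3.71 in AIM-KO and 131 ± 40.2 in WT. Lgals3 changed by -1.93 ± 0.37 (adjusted p = 0.041) and Tyrobp, the adaptor of myeloid receptors, by -0.99 ± 0.18 (adjusted p = 0.04). Among fibrosis genes, Ccn2 and Col3a1 changed by -1.35 ± 0.24 (adjusted p = 0.03) and -1.31 ± 0.25 (adjusted p = 0.043), Col3a1 at 380 ± 135 against 917 ± 216. F2r, the thrombin receptor gene, changed by -1.43 ± 0.24 (adjusted p = 0.026), and Lyve1, an endothelial hyaluronan receptor gene, by -1.13 ± 0.21 (adjusted p = 0.041). Klf6 changed by -1.36 ± 0.23 (adjusted p = 0.026). Cidea changed by -4.26 ± 0.76 (adjusted p = 0.037), at 23.6 ± 19.1 against 781 ± 787. Higher in AIM-KO were the female-biased sulfotransferase gene Sult2a2 (5.72 ± 1.1, adjusted p = 0.041), Asic5 (2.87 ± 0.22, adjusted p = 9.7e-07), the trafficking gene Gga1 (1.88 ± 0.34, adjusted p = 0.04) and the cholesterol synthesis gene Ebp (0.75 ± 0.15, adjusted p = 0.041). The class II gene H2-Aa (-1.39 ± 0.3, adjusted p = 0.063) and Hao2 (2.96 ± 0.65, adjusted p = 0.073) stayed short of the threshold.

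Of the 23 genes called at 20 weeks, 4 were higher and 19 lower, and 1969 genes had an unadjusted p under 0.05. With a term for the Xist-high arrays 6 genes were called, of which Cd5l (-6.41) and Asic5 (2.76) were shared, and the median SE was 0.31. The term took Cidea to -1.85, Lgals3 to -0.95, Ccn2 to -0.99, Col3a1 to -0.99, F2r to -0.82, Klf6 to -0.89, Sult2a2 to 1.71 and Ebp to 0.29, and left Mmp12 at -1.99, Tyrobp at -0.96, Lyve1 at -1.2 and Gga1 at 1.82, none past the threshold. Cd5l and Asic5 were called in all 6 fits that left out an array, and the other 12 genes named here in some of them. The count was 946 without the Xist-high WT replicate 2 and 706 with array weights, of which 45.3% and 46.6% were higher, against 17.4%. It was 2 without WT replicate 1 or 3, and 7, 3 and 2 without AIM-KO replicates 1, 2 and 3. With the actin term it was 2.

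Recruited macrophage markers were lower in AIM-KO at 20 weeks, with a median change of -0.66 (adjusted p = 5.5e-08, adjusted p = 0.091 with an estimated correlation), with 3 of 15 called and 11 lower adjusted over the list alone. Their change was -0.64 with the Xist term (adjusted p = 1.4e-07) and -0.65 with the actin term (adjusted p = 5.1e-09). Fibrosis genes were lower, at -0.62 (adjusted p = 1.2e-08, adjusted p = 0.091 with an estimated correlation), with 2 of 20 called and 8 adjusted over the list alone. With either term their change was -0.45 (adjusted p = 2.3e-07 with the actin term). Against WT chow, the fibrosis genes stood at 1.55, 1.37 and 1.54 on the WT arrays and 0.82, 1.08 and 0.7 on the AIM-KO arrays. Endothelium markers were lower, at -0.19 (adjusted p = 0.021, adjusted p = 0.4 with an estimated correlation), with 1 of 12 called and 2 adjusted over the list alone. That call ended without WT replicate 2 or 3 or AIM-KO replicate 3 (-0.18, -0.13 and -0.16, adjusted p = 0.17, 0.059 and 0.071), with the mean of probe sets (-0.13, adjusted p = 0.06) and with array weights (-0.1, adjusted p = 0.22). Cytokine and chemokine genes were lower, at -0.34 (adjusted p = 0.0032, adjusted p = 0.27 with an estimated correlation), with 0 of 20 called and 1 adjusted over the list alone, and at -0.53 with the Xist term. The call ended without WT replicate 2 (-0.29, adjusted p = 0.17). Cell cycle genes were lower, at -0.55 (adjusted p = 0.003, adjusted p = 0.41 with an estimated correlation), with 0 of 22 called over all genes or adjusted over the list alone. Their change was -0.36 with a pseudocount of 13.2, and the call ended without AIM-KO replicate 3 (-0.24, adjusted p = 0.084) and with the Xist term (-0.2, adjusted p = 0.31). Female-biased genes were higher by 1.83 (adjusted p = 0.00055, adjusted p = 0.11 with an estimated correlation), with 0 of 6 called and 3 adjusted over the list alone, by 0.83 with no dim filter, by 0.84 with the actin term and by 0.11 with the Xist term (adjusted p = 0.66). The interferon response list changed by 0.05 (adjusted p = 0.94). In all, 15 of 35 lists were called.

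**Figure D3:**
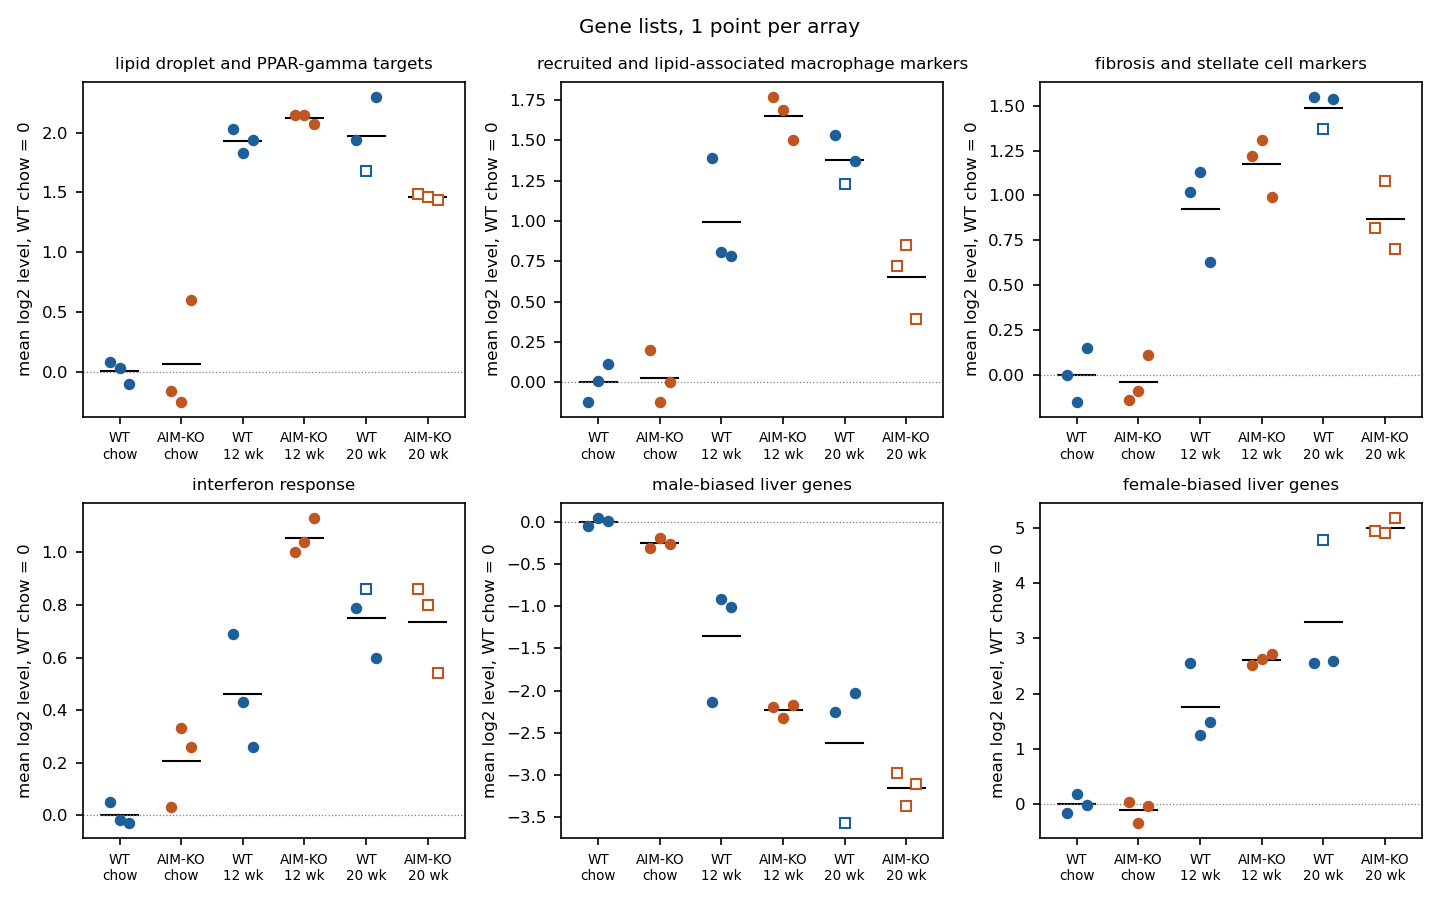
Mean log2 level of gene lists on each array relative to WT chow, by genotype and diet, with points for single arrays. Recruited macrophage markers reach 1.77 in AIM-KO at 12 weeks and lie between 0.39 and 0.85 in AIM-KO at 20 weeks, where the WT arrays lie between 1.23 and 1.53.

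Averaged over the 3 diets, AIM-KO differed from WT in Cd5l (-6.39 ± 0.2, adjusted p = 3.6e-13), Asic5 (2.89 ± 0.13, adjusted p = 6.9e-11), Papss1 (-0.68 ± 0.08, adjusted p = 0.00051) and Hsd3b3 (-0.85 ± 0.13, adjusted p = 0.019), with 9 arrays per genotype. All 4 lie on chromosome 3. Hsd3b3 was called in 10 of the 18 fits that left out an array and the other 3 genes in all 18. Unadjusted p was under 0.05 for 994 genes. The count was 8 without WT 12 weeks replicate 1, 55 without WT 20 weeks replicate 2 (23 higher and 32 lower) and 11 without WT 20 weeks replicate 3. Among 13 tested genes of the 40 nearest neighbours of Cd5l, the median change was 0.09 (2-sided permutation p = 0.11 against 10000 random lists). Interferon response genes were higher in AIM-KO by 0.26 (adjusted p = 2.9e-11, adjusted p = 0.087 with an estimated correlation), with 0 of 21 called and 4 adjusted over the list alone. Markers of T and NK cells were higher by 0.41 (adjusted p = 0.002, adjusted p = 0.087 with an estimated correlation), with 0 of 9 called and 1 adjusted over the list alone, and by 0.27 with a pseudocount of 13.2. Male-biased genes were lower, at -0.4 (adjusted p = 2.6e-05, adjusted p = 0.14 with an estimated correlation), with 0 of 9 called and 4 adjusted over the list alone, at -0.14 with the actin term and at -0.03 with the Xist term (adjusted p = 0.09). In all, 8 of 35 lists were called.

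The difference of the diet effect between genotypes cannot be told from sex at 20 weeks, given the Xist-high arrays. At 12 weeks Hsd3b2 was the single gene called (-2.38 ± 0.34, adjusted p = 0.02), with intensities of 357 ± 9.44 on chow and 264 ± 53 at 12 weeks in WT, and 751 ± 297 and 97.8 ± 20.6 in AIM-KO. The call ended without any 1 WT chow array (adjusted p = 0.057, 0.08 and 0.088 for replicates 1, 2 and 3), WT 12 weeks replicate 3 or AIM-KO 12 weeks replicate 1 or 2 (adjusted p = 0.11 each). The count was 0 in those fits, 23 without WT 12 weeks replicate 1, and 2 without WT 12 weeks replicate 2, AIM-KO 12 weeks replicate 3 or AIM-KO chow replicate 1 or 2. At 20 weeks limma called 0 genes, with 1504 at an unadjusted p under 0.05 and 1386 at 12 weeks. That count was 332 without WT 20 weeks replicate 2, 4 without AIM-KO chow replicate 2, 2 without WT chow replicate 1, and 1 without AIM-KO chow replicate 1 or WT 20 weeks replicate 1. Recruited macrophage markers responded more in AIM-KO at 12 weeks, by 0.5 (adjusted p = 0.00097, adjusted p = 0.26 with an estimated correlation), and less at 20 weeks, at -0.63 (adjusted p = 8.3e-07, adjusted p = 0.1 with an estimated correlation). The first value was 0.26 with the mean of a gene's probe sets and 0.3 without WT 12 weeks replicate 3. Fibrosis genes responded less at 20 weeks, at -0.61 (adjusted p = 2.7e-06, adjusted p = 0.11 with an estimated correlation), and at -0.39 with the Xist term. In all, 10 lists were called at 12 weeks and 11 at 20 weeks.

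Between 12 and 20 weeks, averaged over the genotypes, Xist and the female-biased genes Hao2 and Cyp2b13 were among the 7 named genes, and the 4 Xist-high arrays all lie at 20 weeks. Xist rose by 4.99 ± 0.76 (adjusted p = 0.01), with 6 arrays per duration. Ccn2 rose by 1.11 ± 0.17 (adjusted p = 0.01) and Vldlr by 0.73 ± 0.12 (adjusted p = 0.015), whereas Alas2 changed by -1.19 ± 0.17 (adjusted p = 0.0093) and Cidea by -2.65 ± 0.54 (adjusted p = 0.032). Hao2 and Cyp2b13 rose by 2.71 ± 0.46 and 3.32 ± 0.56. With the Xist term the changes were 1.48 for Ccn2, 0.48 for Vldlr, -0.4 for Alas2, -0.24 for Cidea, 0.7 for Hao2 and 0.48 for Cyp2b13, none past the threshold. Xist, Ccn2 and Alas2 were called in all 12 fits that left out an array, and none of the 3 without a variance trend. Of 82 called genes, 48 were higher and 34 lower. With the Xist term 1 gene was called and 0 of the 82 were shared. The count was 12 without WT 12 weeks replicate 3, 44 without WT 20 weeks replicate 2, 11, 21 and 32 without AIM-KO 12 weeks replicates 1, 2 and 3, and 19, 9 and 20 without AIM-KO 20 weeks replicates 1, 2 and 3. Female-biased genes rose by 2.29 (adjusted p = 4e-08, adjusted p = 0.053 with an estimated correlation), with 4 of 6 called and 5 adjusted over the list alone. That call ended with the Xist term (0.44, adjusted p = 0.24) and in WT alone (1.12, adjusted p = 0.086). In all, 15 of 35 lists were called.

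**Figure D4:**
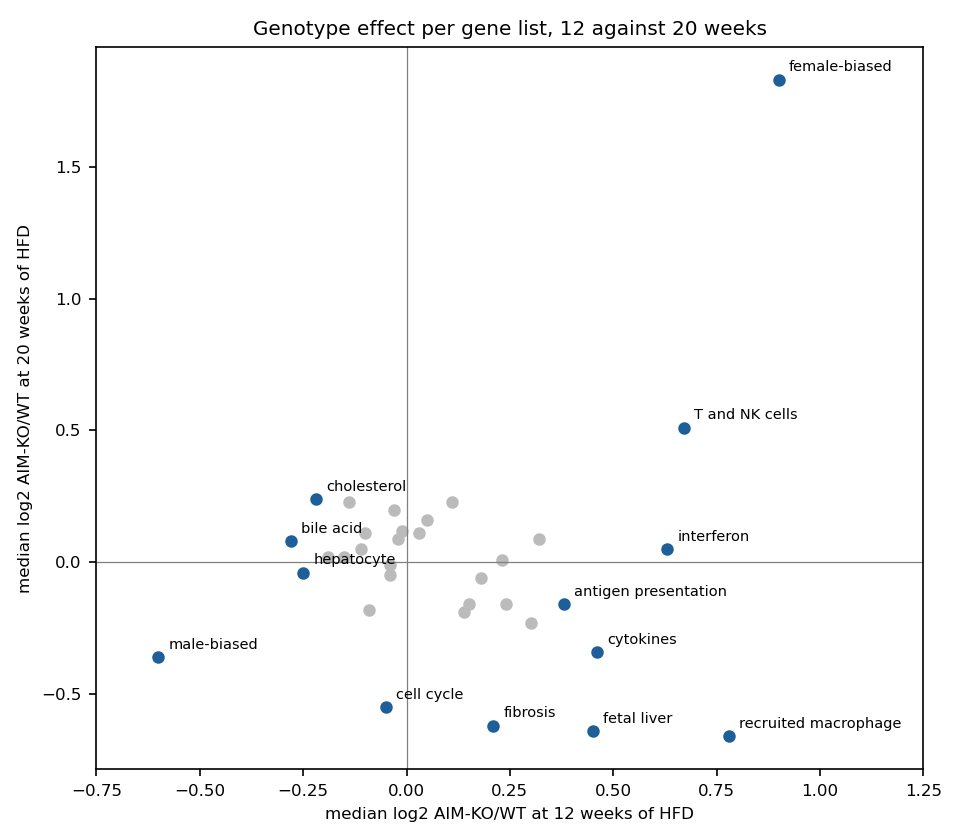
Median log2 change of each gene list between AIM-KO and WT at 20 weeks against that at 12 weeks, 1 point per list. Recruited macrophage markers lie at 0.78 at 12 weeks and -0.66 at 20 weeks, and interferon response genes at 0.63 and 0.05.

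Across all comparisons 161 of 385 list tests passed, and 2 of them passed with the estimated correlation. No called list differed in sign between its median, its mean and its test.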

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

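The tests with a term for the Xist-high arrays or the actin 3'/5' ratio, those in chow and 12 week arrays alone, and those of the hepatocyte share and of strain DNA around Cd5l were chosen only after the result was seen.

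The diet effect at 12 weeks differed between AIM-KO and WT livers, by a test of the difference itself, for 1 gene and 10 lists. For the gene, Hsd3b2, the difference was -2.38 ± 0.34 (adjusted p = 0.02), and it was called in 6 of the 12 fits that left out an array. Recruited macrophage markers (0.5, adjusted p = 0.00097, adjusted p = 0.26 with an estimated correlation) and interferon response genes (0.34, adjusted p = 0.00099, adjusted p = 0.29 with an estimated correlation) differed upward. Bile acid genes (-0.36, adjusted p = 0.00075, adjusted p = 0.11 with an estimated correlation) and male-biased genes (-0.35, adjusted p = 0.01, adjusted p = 0.37 with an estimated correlation) differed downward. The same held for hepatocyte markers (-0.24, adjusted p = 2.7e-05, adjusted p = 0.32 with an estimated correlation) and the respiratory chain (-0.16, adjusted p = 0.00044, adjusted p = 0.22 with an estimated correlation). Those 6 list calls were kept in all 12 fits that left out an array, but their values moved and 3 of them ended after quantile normalization, the male-biased (-0.26, adjusted p = 0.083), hepatocyte (-0.04, adjusted p = 0.2) and respiratory chain lists (-0.03, adjusted p = 0.59). The male-biased value was -0.57 and -0.12 without AIM-KO chow replicates 1 and 3, -0.66, -0.15 and -0.22 without WT 12 weeks replicates 1, 2 and 3, -0.19 without AIM-KO 12 weeks replicate 2 and -0.22 with the actin term. The macrophage value was 0.3 without WT 12 weeks replicate 3 and 0.26 with the mean of probe sets, the interferon value 0.54 without WT 12 weeks replicate 1, and the hepatocyte value -0.15 without WT chow replicate 1. Endothelium markers differed by 0.26 (adjusted p = 0.0046, adjusted p = 0.3 with an estimated correlation), a call that ended without WT 12 weeks replicate 2 (0.23, adjusted p = 0.099) and with array weights (0.19, adjusted p = 0.074), and by 0.4 with the mean of probe sets. Cytokines differed by 0.55 (adjusted p = 0.03, adjusted p = 0.41 with an estimated correlation), and without WT 12 weeks replicate 3 by 0.27 (adjusted p = 0.29). That call also ended without AIM-KO chow replicates 2 and 3 (0.35 and 0.46, adjusted p = 0.084 and 0.082) and AIM-KO 12 weeks replicate 1 (0.44, adjusted p = 0.098), with a pseudocount of 0.825 (0.59, adjusted p = 0.056) and with the stricter dim filter (0.52, adjusted p = 0.054). Target genes of p53 differed by 0.31 (adjusted p = 0.043, adjusted p = 0.16 with an estimated correlation), a call lost without WT chow replicate 1 or 3, AIM-KO chow replicate 1, WT 12 weeks replicate 3 or AIM-KO 12 weeks replicate 3 (0.38, 0.28, 0.44, 0.15 and 0.26, adjusted p = 0.067 to 0.15), and their difference was 0.12 without AIM-KO chow replicate 3. It was lost as well with the stricter dim filter, the mean of probe sets, no variance trend, array weights, only the groups compared, the Xist term and without the 4 Xist-high arrays (0.16 to 0.34, adjusted p = 0.051 to 0.072). Xenobiotic cytochromes P450 differed by -0.14 (adjusted p = 0.049, adjusted p = 0.5 with an estimated correlation), a call lost without any of 8 arrays (adjusted p = 0.058 to 0.23), namely WT chow replicates 1 and 3, AIM-KO chow replicates 2 and 3, WT 12 weeks replicates 2 and 3 and AIM-KO 12 weeks replicates 1 and 2. With 1 array left out their difference ran from -0.29 (AIM-KO chow replicate 1) to -0.01 (WT chow replicate 1), with -0.24 without WT chow replicate 2 and -0.08 without WT 12 weeks replicate 2. That call was lost in 9 of the other settings too, among them quantile normalization (-0.12, adjusted p = 0.59) and array weights (-0.07, adjusted p = 0.064).

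By the same test, the 20 week diet effect, not separable from sex, differed for 11 lists. Recruited macrophage markers (-0.63, adjusted p = 8.3e-07, adjusted p = 0.1 with an estimated correlation), fibrosis genes (-0.61, adjusted p = 2.7e-06, adjusted p = 0.11 with an estimated correlation) and antigen presentation genes (-0.32, adjusted p = 0.0014, adjusted p = 0.18 with an estimated correlation) differed downward. So did cytokines (-0.28, adjusted p = 0.00033, adjusted p = 0.17 with an estimated correlation) and cell cycle genes (-0.65, adjusted p = 0.00034, adjusted p = 0.31 with an estimated correlation). Female-biased genes differed by 2.03 (adjusted p = 0.0029, adjusted p = 0.15 with an estimated correlation), by 1.26 with no dim filter, by 1.2 with the actin term and by 0.6 with the Xist term, which ended the call (adjusted p = 0.57). These 6 list calls were kept in all 12 fits that left out an array, with moved values for some. Cytokines differed by -0.61 without AIM-KO chow replicate 2, by -0.73 with the mean of probe sets and by -1.01 with the Xist term. Cell cycle genes differed by -0.39 without AIM-KO 20 weeks replicate 3, by -0.43 with a pseudocount of 13.2 and by -0.25 with the Xist term. The fibrosis value was -0.39 with the Xist term, and the antigen presentation value -0.17 without AIM-KO chow replicate 1, with its call ended by array weights (-0.4, adjusted p = 0.098). Cholesterol synthesis genes differed by 0.51 (adjusted p = 0.00015, adjusted p = 0.42 with an estimated correlation), by 0.25 without WT chow replicate 1 (adjusted p = 0.077) and by 0.33 with the actin term. Fatty acid oxidation genes differed by 0.34 (adjusted p = 0.0014, adjusted p = 0.38 with an estimated correlation), by 0.13 without AIM-KO chow replicate 1 (adjusted p = 0.073), by 0.17 with the actin term and by 0.18 with the Xist term (adjusted p = 0.46). For xenobiotic cytochromes P450 the difference was 0.34 (adjusted p = 0.0061, adjusted p = 0.34 with an estimated correlation), and the call ended without WT chow replicate 2 (0.19, adjusted p = 0.059) and with the Xist term (0.04, adjusted p = 0.5). Their value was 0.56 with the mean of probe sets, 0.21 and 0.62 without WT chow replicates 1 and 3, 0.21, 0.21 and 0.57 without AIM-KO chow replicates 1, 2 and 3, 0.04 and 0.72 without WT 20 weeks replicates 1 and 2, and 0.54 and 0.07 without AIM-KO 20 weeks replicates 2 and 3. Lipid droplet genes differed by -0.19 (adjusted p = 0.022, adjusted p = 0.43 with an estimated correlation), by 0.07 without AIM-KO chow replicate 3 (adjusted p = 0.41) and by -0.1 without WT 20 weeks replicate 3 (adjusted p = 0.083). That difference was -0.36 without AIM-KO chow replicate 1, -0.32 without WT 20 weeks replicate 2, -0.11 with array weights (adjusted p = 0.22) and -0.02 with the Xist term (adjusted p = 0.21). Fetal liver and tumour markers differed by -0.77 (adjusted p = 0.029, adjusted p = 0.22 with an estimated correlation), a call lost without WT chow replicate 1, AIM-KO chow replicate 1, WT 20 weeks replicate 2 or AIM-KO 20 weeks replicate 3 (-0.67, -0.31, -0.35 and -0.78, adjusted p = 0.052 to 0.1) and with array weights (-0.37, adjusted p = 0.053).

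Probe sets with several genes or none in the annotation stand outside the comparisons of the report, and 5969 of them passed the dim filter. Tested in the same way, 1 of them was called for AIM-KO against WT on chow, 3 at 12 weeks, 6 at 20 weeks and 1 averaged over the diets. For the diet in WT 50 were called at 12 weeks and 223 at 20 weeks, and in AIM-KO 280 and 160.

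The first pattern weighed is the higher level of recruited macrophage and interferon genes in AIM-KO at 12 weeks of HFD, by 0.78 and 0.63, which markers of T and NK cells accompanied at 0.67. A uniformly stronger response, taken off with the slope on the WT diet effect at 20 weeks (0.181, r = 0.3), left 0.51 and 0.43, at percentile 100 of random lists matched on expression. A slope on noisy effects takes off too little, so this cannot decide. A lower hepatocyte share would raise other cell type markers alike, but endothelium and bile duct genes changed by 0.15, less than macrophage and interferon genes (permutation p = 0.0089 and 0.0074, treating genes as independent). Also open is a hypothesis of more macrophages or other immune cells, or of a stronger interferon response, without AIM, found and tested on the same data, and the adjusted p with an estimated correlation was 0.091 for macrophage, 0.063 for interferon and 0.1 for T and NK genes. Of the 10 splits of the 6 arrays, 1, the real one, called 11 genes and the highest other 1, and 10 splits are too few for a share under 0.05.

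Lower recruited macrophage and fibrosis genes in AIM-KO at 20 weeks, at -0.66 and -0.62 (adjusted p = 0.091 each with an estimated correlation), are the second pattern, and endothelium markers were lower with them, at -0.19 (adjusted p = 0.4 with an estimated correlation), a call that ended without WT replicate 2 or 3 or AIM-KO replicate 3 (-0.18, -0.13 and -0.16). A uniformly weaker response, taken off with the slope on the WT diet effect at 12 weeks (-0.218, r = -0.26), left -0.48 and -0.5, at percentile 0 of matched random lists, and again cannot decide. The actin term for RNA quality left -0.65 and -0.45 but 2 of 23 gene calls. The ratio was 2.35 to 2.61 on the Xist-high arrays and 3.64 and 4.22 on the other WT arrays. The Xist term left -0.64 and -0.45, yet it rests on 1 WT array and all AIM-KO arrays are Xist-high. So RNA quality, sex and genotype cannot be told apart for these lists. Female-biased genes fell from 1.83 to 0.11 with the same term, consistent with sex as the source of that change. Of the 10 splits 1, the real one, called 23 genes and the highest other 1, too few splits for a share under 0.05.

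The third pattern is that all 4 genes called on chow, all 4 called over the 3 diets, 4 of 11 at 12 weeks and 3 of 23 at 20 weeks (Cd5l, Asic5 and Setd7, the last at -1 ± 0.17 and chosen after its values were seen) lie on chromosome 3. Sex of the animals would remove the excess in the chow and 12 week arrays alone, but there 9 of 191 tested genes among the 300 nearest on each side of Cd5l had p under 0.01 against 247 of 13874 on other chromosomes (Fisher's exact p = 0.0083). DNA of another strain kept around Cd5l stays open, because the shares over the 3 diets were 9 of 191 near it and 23 of 535 on the rest of the chromosome (Fisher's exact p = 0.84), each above the 197 of 13874 elsewhere (exact p = 0.002 and 7.6e-06). Near Cd5l the share was 4.7% at 12 weeks and 3.7% at 20 weeks, against 2.5% and 4.7% elsewhere (exact p = 0.061 and 0.61). Sequence variants under single probe sets cannot be told from changed expression, as the genes near Cd5l had 5 other probe sets, of which 40% changed the same way. An effect of AIM loss on these genes was not tested apart from their location and stays open.

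Other splits of the arrays were counted for each further comparison. On chow 1 of 10 splits, the real one, called 4 genes and the highest other called 1. For the diet, 1 of 10 splits, the real one, gave 753 genes in WT at 12 weeks (highest other: limma 0), 2123 in WT at 20 weeks (4), 2645 in AIM-KO at 12 weeks (limma 0) and 1007 in AIM-KO at 20 weeks (1), and 10 splits are too few for a share under 0.05 in each. Over the diets only the real split of 100 called 4 genes, Cd5l by design (highest other 1), which tests no single gene. For 20 against 12 weeks 7 of 100 called at least the real 82, so chance is open. The highest other called 746 and put the 4 Xist-high arrays in 1 group with WT 12 weeks replicates 1 and 3, which points to a structure of the samples, and with the Xist term 1 gene was called. For the difference of the 12 week diet effect 6 of 100 splits called 1 gene, the real count and the highest other, so chance is open. For that of the 20 week effect limma called 0 genes (1504 at an unadjusted p under 0.05), all 100 splits called as many and the highest other called 16, so chance is open there, and whether that split follows a structure of the samples was not tested.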

How the results depend on the processing

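The tests with the Xist term or the actin term, those without the 4 Xist-high arrays, in chow and 12 week arrays alone and in WT alone were chosen only after the result was seen; the other alternatives were chosen before the data were examined.

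Depth and number of arrays limit the results as follows. The median intensity was 15 to 21.1 per array and the pseudocount 3.3, so changes of dim genes are understated and depend on the pseudocount. Groups of 3 arrays gave a median standard error of 0.22. The change of Cd5l averaged over the diets stayed between -5.58 and -6.71 under every alternative. Of the 161 called lists, 139 to 158 stayed past the threshold in the same direction under each planned setting that left the list test and the arrays as they were, lowest with array weights and highest with no dim filter. With the estimated correlation 2 did. Of the 137 calls of genes named in the text, all 137 were kept with array weights, a pseudocount of 13.2 and the stricter dim filter. With no variance trend 106 were kept, with only the groups compared 115, with the mean of probe sets 116, with no dim filter 122, with a pseudocount of 0.825 132 and after quantile normalization 133. The Xist term kept 119 of 161 lists and 115 of 137 genes, the actin term 148 and 119. Without the 4 Xist-high arrays 88 of 92 lists and 90 of 92 genes were kept, in chow and 12 week arrays alone 6 of 8 and 4 of 4, and in WT alone 2 of 15 and 1 of 7. Leaving out 1 array kept calls in 1153 of 1278 list tests and 786 of 918 gene tests.

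For the other counts the cause was not tested, except where fewer genes or arrays enter by construction. A pseudocount of 13.2 gave 19 genes for AIM-KO against WT at 12 weeks and 35 at 20 weeks, and correlations of the diet effects of the genotypes of 0.69 and 0.64. A pseudocount of 0.825 gave correlations of 0.53 and 0.51. Quantile normalization gave 7 genes at 12 weeks (28.6% higher, against 54.5%) and 2 for the difference of the 20 week diet effect, and took the share higher at 20 weeks from 17.4% to 25.8%. Without the dim filter there were 5 genes at 12 weeks and 9 at 20 weeks, with correlations of 0.53 and 0.5. With the stricter dim filter, which tests fewer genes, the difference of the 20 week diet effect had 6 genes and the correlations were 0.75 and 0.69. The mean of a gene's probe sets gave 6 genes at 12 weeks, 2 at 20 weeks and 46 for 20 against 12 weeks. With no variance trend there were 3 at 12 weeks, 2 at 20 weeks, 2 for 20 against 12 weeks and 0 by limma for the difference of the 12 week diet effect (1386 at an unadjusted p under 0.05 with the trend). Array weights gave 9 genes on chow, 67 at 12 weeks, 706 at 20 weeks and 18 averaged over the diets. For the diet they gave 1314 in WT at 12 weeks, 4229 in AIM-KO at 12 weeks and 1986 in AIM-KO at 20 weeks. They gave 273 for 20 against 12 weeks, and 19 and 67 for the differences of the 12 and 20 week diet effects. With only the groups compared in the fit, so fewer arrays, there were 4 genes at 12 weeks, 9 at 20 weeks, 1369 for WT at 20 weeks against chow and 0 by limma for the difference of the 12 week diet effect. A minimum fold of 1.5 left 53 genes for 20 against 12 weeks.

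With the Xist term, chosen after seeing the data like the other alternatives of this paragraph, there were 6 genes for AIM-KO against WT at 20 weeks, 195 for the diet in AIM-KO at 20 weeks, 1 for 20 against 12 weeks, 3 and 2 for the differences of the 12 and 20 week diet effects, and a correlation of 0.65 at 20 weeks. Without the 4 Xist-high arrays the difference of the 12 week diet effect had 2 genes. The actin term gave 6 genes at 12 weeks, 2 at 20 weeks and 135 for 20 against 12 weeks. The chow and 12 week arrays alone gave 8 genes over the diets, 4 of them shared, and WT alone 1 gene for 20 against 12 weeks. The cause was not tested.

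Directions, for lists those of the list test, turned as follows, with medians in brackets, and the cause was not tested. Cholesterol synthesis genes on chow, lower with all arrays, turned without WT chow replicate 1 while their median stayed negative (-0.01; -0.41 to -0.01 with 1 array left out). With the Xist term fatty acid oxidation genes turned at 20 weeks (0.01, still positive), as did the sex chromosome list in AIM-KO against WT at 20 weeks (0.11), for the diet in AIM-KO (0.2) and for 20 against 12 weeks (0.11). For the diet in AIM-KO at 20 weeks Eif2s3y turned (0.18), and the neutrophil test turned with a positive median (0.18). For 20 against 12 weeks the tests of xenobiotic cytochromes P450 (-0.08) and, with medians still negative, of lipid droplet (-0.06) and male-biased genes (-0.03) turned. In chow and 12 week arrays alone fibrosis genes averaged over the diets turned to 0.06. In WT alone, for 20 against 12 weeks, the lists that turned were macrophage (0.49, adjusted p = 0.0019), lipid droplet (0.23), antigen presentation (0.12), cell cycle (0.14), NRF2 target (0.02), cytochrome P450 (-0.11, adjusted p = 0.0096) and sex chromosome genes (0.13), and Cidea turned to 0.29. For respiratory chain and hepatocyte genes the test alone turned, and medians fell to 0 and 0.02.

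Leaving out 1 array at a time, which removes samples, gave counts for AIM-KO against WT of 3 to 7 on chow, 3 to 100 at 12 weeks, 2 to 946 at 20 weeks and 3 to 55 averaged over the diets. For the diet they were 334 to 742 in WT at 12 weeks, 1397 to 2458 in WT at 20 weeks, 1696 to 2340 in AIM-KO at 12 weeks and 538 to 994 in AIM-KO at 20 weeks. For 20 against 12 weeks they were 9 to 117, and for the differences of the diet effect 0 to 23 at 12 weeks and 0 to 332 at 20 weeks (unadjusted counts with all arrays 1386 and 1504, by limma). The averaged change of Cd5l ran from -6.53 to -6.25, the called lists from 153 to 165, and the correlations from 0.49 to 0.6 at 12 weeks and 0.48 to 0.57 at 20 weeks. The median change of the neighbours of Cd5l ran from 0.05 to 0.15, and it passed the threshold without AIM-KO 12 weeks replicate 1 (permutation p = 0.023) and without AIM-KO 20 weeks replicate 2 (permutation p = 0.033).

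Pairing of samples by replicate number stays open. Over 45 pairs of arrays with the same number the correlation of residuals was -0.09 to 0.23 (mean 0.04, 3 over 0.1, all of replicate 3). With a replicate block the counts were 17 at 12 weeks and 63 at 20 weeks for AIM-KO against WT, from 11 and 23. They were 2 and 5 for the differences of the 12 and 20 week diet effects. Other counts stayed within 1.5 times.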

Other observations

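The comparison of the genotype effect between 20 and 12 weeks, its other splits and its tests with the Xist term were chosen only after the result was seen.

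Among the HFD arrays, the AIM-KO to WT change at 20 weeks was compared directly with that at 12 weeks. The difference was -1.46 for recruited macrophage markers (adjusted p = 3.4e-11, adjusted p = 0.061 with an estimated correlation), -0.84 for cytokines and chemokines (adjusted p = 1.9e-07, adjusted p = 0.061 with an estimated correlation) and -0.82 for fibrosis genes (adjusted p = 2.9e-07, adjusted p = 0.063 with an estimated correlation). Interferon response genes differed by -0.45 (adjusted p = 7.3e-06, adjusted p = 0.11 with an estimated correlation), antigen presentation genes by -0.53 (adjusted p = 1e-04, adjusted p = 0.096 with an estimated correlation) and fetal liver and tumour markers by -1.27 (adjusted p = 0.00057, adjusted p = 0.063 with an estimated correlation). Bile acid genes differed upward, by 0.54 (adjusted p = 7.3e-06, adjusted p = 0.061 with an estimated correlation), as did cholesterol synthesis genes, by 0.52 (adjusted p = 4.6e-05, adjusted p = 0.34 with an estimated correlation). With the Xist term the values were -1.38 for macrophage, -1.14 for cytokine, -0.67 for fibrosis, -0.71 for interferon, -0.49 for antigen presentation, -1 for fetal liver, 0.34 for bile acid and 0.37 for cholesterol genes, each with an adjusted p of at most 0.0019. Calls that ended with the term were cell cycle genes (-0.59, adjusted p = 0.021, to -0.14, adjusted p = 0.39) and NRF2 targets (-0.36, adjusted p = 0.013, to -0.19, adjusted p = 0.17), each with adjusted p of 0.34 or more with an estimated correlation. Endothelium markers differed by -0.3 (adjusted p = 0.0047, adjusted p = 0.27 with an estimated correlation) and hepatocyte markers by 0.23 (adjusted p = 0.00073, adjusted p = 0.34 with an estimated correlation), and by -0.4 and 0.24 with the term. In all, 17 of 35 lists were called. The term rests on 1 WT array. Over all genes 208 were called, 52 of them higher, and 15 with the Xist term. Other alternatives were not run for this comparison. Of 100 splits of the arrays 1, the real one, called that many, and the highest other, which kept the 3 AIM-KO arrays of 20 weeks together, called 149. Since the comparison was picked after lists had been seen to move apart on the same arrays, that count is no independent evidence against chance, and sex of the animals stays open.

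Resident Kupffer cell markers, 17 genes, differed between AIM-KO and WT by 0.15 at 12 weeks (adjusted p = 0.044, adjusted p = 0.51 with an estimated correlation), with 0 of 17 called by limma over all genes and 4 higher and 1 lower adjusted over the list alone. The call ended without WT 12 weeks replicate 3 (0.1, adjusted p = 0.29) or AIM-KO 12 weeks replicate 3 (0.11, adjusted p = 0.35), and the value was 0.23 and 0.25 without WT 12 weeks replicates 1 and 2 and 0.24 without AIM-KO 12 weeks replicate 1. It ended as well with a pseudocount of 13.2, the stricter dim filter, no variance trend, array weights, only the groups compared, the Xist term, the actin term and without the 4 Xist-high arrays (adjusted p = 0.05 to 0.31). At 20 weeks the change was -0.16 (adjusted p = 0.069), and -0.46 with the Xist term, resting on 1 WT array.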
